A study of Homo sapiens with 16 samples.

How the data were processed

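RNA was measured in HCC70 cells, an established human breast cancer line of the basal-like, triple-negative kind, after infection with short hairpin RNA (shRNA) constructs, per the labels. The 16 libraries fall into 8 construct groups of 2 libraries. The 4 targeted groups are named for the transcription factors KLF5, RBPJ, NFIB and FOXA1, and each of their libraries carries a different hairpin, per the labels. The 4 control groups are plko, shRFP, shLACZ and shLUC, named for an empty-vector backbone or for genes that human cells lack, so that 8 control libraries stand against 2 libraries of each target. Control constructs were taken as non-targeting from their names. Cells were grown in multiwell plates, RNA was purified with a kit made for single cells, and 3′ cDNA was barcoded in batches of 12 samples before amplification by in vitro transcription in the manner of CEL-Seq, per the labels' protocols. The same protocols say that some samples were run a second time because they were poorly represented in the first run. Which samples these were, and which samples shared a barcoding batch, is not given in the sources used here.

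The authors deposited a single table of 11282 genes, in which the values are a normalized signal, named as DESeq2-normalized in the name of the deposited table. The genome build was GRCh37, per the submitters' processing notes. The aligner, the counting tool, the annotation release, the use of molecular identifiers and any filter on low counts are not given in the sources used here. In each library the deposited values were whole multiples of the value of 1 read, within a tolerance of 0.05 of a read for 100% of the values, so that whole reads were recovered by dividing by that step. No gene had a recovered sum under 23 reads over all columns used, and no gene had a read in fewer than 9 libraries. The table held 2 columns that match no sample described here, and these were not used. Gene symbols came from a table of identifiers and symbols, in which 11259 of the 11282 identifiers were found. The reference annotation at hand was of another build, so no coordinates are given.

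Recovered totals ran from 375713 reads in plko 1 to 3090666 in RBPJ 1, with a median of 1164801.5. The median gene had 11 reads in the shallowest library and 101 in the deepest, and a floor of 3 counts was used for what a count of 0 allows. Floors cover counting error only. Pairs of libraries of a construct differed by more than sampling noise in every group, with a chi-square per degree of freedom of 2.07 to 19.7 on the recovered reads, so all 16 libraries were kept as separate samples. The labels do not say that the 2 libraries of a control construct came from separate cultures, so their spread may be technical. The 2 libraries of a target carry different hairpins, so their spread includes differences between hairpins. The p-values pool both and measure only the spread between these samples.

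The test was limma with a mean-variance trend, on log2 of the deposited value plus a pseudocount of 1, with a factor of 5 levels (all controls together and each target) over all 16 libraries. Genes with a value of at least 5 in at least 2 libraries were kept, which left 10826 genes and removed 456. The Benjamini-Hochberg adjusted p had to be under 0.05, and all tests were 2-sided. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The contrasts were each target against the controls, the mean of the 4 targets against the controls, and the 6 differences between 2 targets. Differences among the 4 control constructs were tested with limma's F test on the 8 control libraries. Single targeted genes were also tested by exact permutation of 2 libraries against 8, which has 45 arrangements and a smallest p of 0.0444.

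Gene lists covered basal keratinocyte-type epithelium, mature luminal epithelium, luminal progenitor, Notch pathway, asymmetric division and polarity, G1/S and DNA replication, mitosis, interferon response, NF-kB and inflammatory cytokines, squamous differentiation, mesenchymal transition, EGF family ligands and immediate MAPK response, YAP/TEAD targets, p53 targets, unfolded protein and integrated stress response, heat shock proteins, hypoxia and glycolysis, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, and replication-dependent histones and short RNAs. The lists, the tests, the rule for naming genes and all alternatives but 2 were chosen before the data were examined. The 21 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, and adjusted over the 84 tests of the 4 targets. Camera with an estimated correlation and fry were alternatives. Lists of mitochondrially encoded genes, of fibroblast and endothelial markers and of leukocyte markers had fewer than 5 tested members, and only values per library are given for them.

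Named genes were, for each target, the targeted gene, up to 12 passing genes per direction with the largest fold change among those with a mean value of at least 10 over the 16 libraries and both hairpins outside the range of the 8 controls, and where fewer than 5 passed, the genes of smallest p up to 5, given as not passing. For the mean of the 4 targets, all 4 target means had to lie on the same side of the control mean in place of the range rule. From each list the up to 4 members of smallest p were added, and KRT14, KRT5, KRT18, KRT8, HES1 and NRARP always. Genes named outside this rule are said to be so. Some genes that the rule selects are not reported here.

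On simulated data with 200 changed genes of 10826, the test recovered 97%, 95%, 95% and 95% of 4-fold changes in comparisons built like those of KLF5, RBPJ, NFIB and FOXA1, and 45%, 39%, 37% and 49% of 2-fold changes, with 8, 2, 9 and 21 false calls. In a simulated FOXA1 comparison with 1 shifted list of 21, camera called the shifted list at an adjusted p of 1.86e-08 and 1 unshifted list. The 200 changed genes were drawn only from genes with a mean value of at least 10, so recovery among lower genes is not known. The simulations gave both hairpins of a target the full change and gave all control constructs the same means. They therefore do not tell how many changes are recovered where hairpins or control constructs differ, as they did here. Each gene was also drawn independently of the others. The list run therefore does not tell how often camera calls unshifted lists whose members vary together.

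Alternatives were pseudocounts of 0.5 and 5, no filter and a filter of 20, TMM factors, quantile normalization, array weights, the compared groups alone, leaving out each control construct or each library in turn, a block for the replicate number, the number of detected genes as a covariate, and count models on the recovered reads in edgeR (quasi-likelihood test) and DESeq2. A further alternative, with plko as the only control of KLF5 and the other 6 control libraries for the other targets, was added after the plko and KLF5 libraries were seen to stand apart together. Another alternative, also added after the data were seen, left the targeted genes out of the lists. Analyses used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.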

Results

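The data describe the transcriptome of HCC70 cells, a basal-like breast cancer line, with hairpins against KLF5, RBPJ, NFIB or FOXA1, or with a control construct. The series asks which regulatory factors shape the mix of cell states in basal-like cancer and the balance of symmetric and asymmetric division. Each of the 8 constructs had 2 libraries, called 1 and 2 here as in the labels, and the 8 control libraries served every target. The recovered totals differed 8.23-fold, from 375713 reads in plko 1 to 3090666 in RBPJ 1. Between 10659 genes (plko 1) and 11282 genes (RBPJ 1) had at least 1 read. Values are the deposited normalized signal, and errors of control values are SD over 8 libraries.

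Each targeted transcript was lower with its hairpins than the mean of the controls, to a different degree in each library. KLF5 (ENSG00000102554), a zinc-finger factor of epithelial cells, was at 62.56 and 37.34 with its hairpins and at 94.82 ± 12.99 in the controls (n = 8), which is 66% and 39.4% of the control mean. NFIB (ENSG00000147862), a nuclear factor I protein, was at 237.81 and 42.19 against 384.49 ± 102.11 (n = 8), or 61.8% and 11%. FOXA1 (ENSG00000129514), a pioneer factor of luminal cells, was at 24.36 and 58.58 against 106.93 ± 36.36 (n = 8), or 22.8% and 54.8%. RBPJ (ENSG00000168214), the DNA-binding partner of Notch receptors, was at 8.53 in RBPJ 2, 16.6% of the control mean of 51.3 ± 7.77 (n = 8). The library labelled RBPJ 1 was at 43.26, inside the control range of 43.12 to 68.39. The log2 fold changes were -0.95 ± 0.21 (SE) for KLF5, -1.34 ± 0.34 for RBPJ, -1.89 ± 0.39 for NFIB and -1.41 ± 0.32 for FOXA1. With limma over all genes only KLF5 passed, at an adjusted p of 0.0122, and the adjusted p was 0.266 for RBPJ, 0.2 for NFIB and 0.257 for FOXA1. Adjusted over the list alone, the 4 targeted genes passed, at adjusted p of 0.000299, 0.000675, 0.000296 and 0.000299 in the order KLF5, RBPJ, NFIB and FOXA1. Exact permutation gave p = 0.0444, the smallest possible, for KLF5, NFIB and FOXA1 and 0.0889 for RBPJ. The KLF5 call was lost without KLF5 2 (log2 fold change -0.58, limma adjusted p 0.348) and with plko as the only control (-0.76, adjusted p 0.101), an alternative chosen after seeing the data. RBPJ passed over all genes without RBPJ 1 (-2.44, adjusted p 0.000195), was at -0.23 without RBPJ 2, and NFIB passed without NFIB 1 (-3.12, adjusted p 0.000144) and was at -0.65 without NFIB 2. FOXA1 was at -0.79 without FOXA1 1 and -2.02 without FOXA1 2. Wherever a library of a target is left out, the other is a lone sample that is assumed to vary like the other groups.

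**Figure D1:**
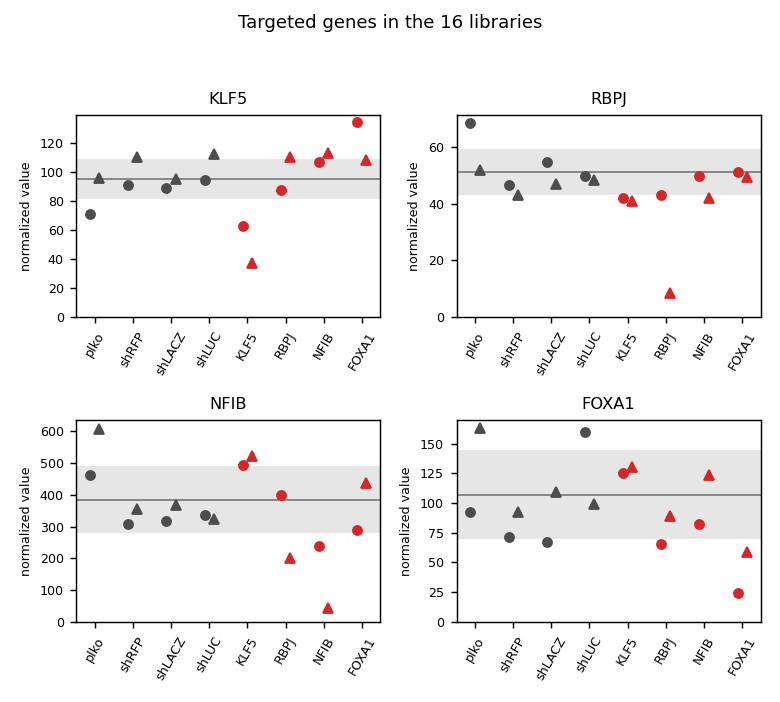
Deposited normalized values of KLF5, RBPJ, NFIB and FOXA1 (vertical axes) in the 16 libraries by construct (horizontal axes), with grey symbols for control and red for targeting constructs, circles for library 1 and triangles for library 2, a line at the mean of the 8 controls and a band of 1 SD on either side. The library labelled RBPJ 1 lies at 43.26 for RBPJ, inside the control range of 43.12 to 68.39, and RBPJ 2 lies at 8.53.

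The control constructs were compared because they give the background of every other comparison. KRT8, a keratin of simple and luminal epithelium, averaged 18.2 in the plko libraries and 237, 180 and 241 in the shRFP, shLACZ and shLUC libraries (limma F test, adjusted p = 4.94e-09, n = 2 each). ACTB, cytoplasmic beta-actin, averaged 515 in plko and 2035, 1863 and 2118 in the others (adjusted p = 2.36e-05). PKP3, a desmosomal plakophilin, averaged 33.6 in plko and 180, 133 and 132 in the others (adjusted p = 3.65e-05). AZGP1, a secreted zinc-binding glycoprotein, averaged 915 in plko and 343, 470 and 220 in the others (adjusted p = 0.000154). These 4 genes were named after their values were seen. Over all genes 326 differed among the control constructs. The plko libraries differed from the other 6 control libraries at 1019 genes, 307 higher and 712 lower. The shRFP, shLACZ and shLUC libraries each differed from the remaining controls at 0 genes by limma, with 320, 556 and 313 genes at an unadjusted p under 0.05. The remaining controls included plko, which widens their spread, so these counts do not show that the 3 constructs are alike. The count of 326 became 931 without plko 2, 102 and 129 without shRFP 1 and shRFP 2, 172 without shLACZ 1, and 202 and 185 without shLUC 1 and shLUC 2.

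The KLF5 comparison asked which genes move when this epithelial factor is targeted, and 581 genes passed, 249 higher and 332 lower. FGFBP1, a secreted carrier of fibroblast growth factors, fell by 2.24 on the log2 scale (SE 0.28, limma adjusted p = 0.000125), to 15.6 and 10.5 from 66.2 ± 18.4 (n = 8). IVL, a precursor of the cornified envelope, fell to 2.13 and 3.5 from 24.3 ± 14.8, and AQP3, a water and glycerol channel, to 9.95 and 7 from 52 ± 21. ACTB fell to 161 and 275 from 1633 ± 724, and KRT8 to 13.5 and 12.8 from 169 ± 97. The sialyltransferase ST3GAL4 fell to 3.55 and 3.5 from 30.1 ± 15.6. MB, which encodes the oxygen-binding protein myoglobin, fell to 2.84 and 4.67 from 20.6 ± 6.98. VARS1, a valyl-tRNA synthetase, rose by 2.07 on the log2 scale (SE 0.23, adjusted p = 0.000107), to 215 and 183 from 47.5 ± 10.4. VIM, the intermediate filament of mesenchymal cells, rose to 157 and 211 from 48.5 ± 33, and CARM1, an arginine methyltransferase, to 446 and 322 from 131 ± 32.9.

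Other genes that rose with the KLF5 hairpins included CPSF1, a subunit of the polyadenylation machinery (log2 1.61), INTS1, of the Integrator complex (1.61), SUPT6H, a histone chaperone of elongating polymerase (1.61), UCKL1, a uridine kinase relative (1.72), and ZNF771, a zinc-finger protein (1.70), with limma adjusted p of 0.00109 to 0.0269. JSRP1, COCH, BEST1 and PLD3 rose as well, by 2.18, 2.06, 1.90 and 1.60. IFITM1, an interferon-induced membrane protein, was at 0 and 1.17 with the KLF5 hairpins and at 44.7 ± 33.4 in the controls, and RPS25 at 0 and 3.5 against 29.2 ± 10.9. RPS27 was at 0.71 and 5.83 against 26.9 ± 11.4. These 3 genes passed the test as lower, and no fold is given because their values rest on few reads. IVL, at 2.13 and 3.5, lay at the value of 3 reads in both KLF5 libraries. MB (2.84 and 4.67) and ST3GAL4 (3.55 and 3.5) lay near it, so the folds of IVL, MB and ST3GAL4 are uncertain too. H4C3 (log2 -2.05) and RPL14 (-2.46) also passed as lower, but reads of histone and ribosomal protein genes can be shared with near-identical copies, so these values are uncertain. Both KLF5 libraries lay outside the control range for 16.28% of genes, where chance gives 4.44%.

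The plko and KLF5 libraries stood apart from the other 12 together: 412 of 8346 genes had all 4 of these libraries below or above all others, against 9.2 by chance and 43 for the next pair of constructs. KRT8 was at 22.1 and 14.3 in plko 1 and plko 2, close to the KLF5 libraries. With plko as the only control, chosen after seeing the data, 372 genes passed, 246 higher and 126 lower, of which 192 were among the 581 and had the same direction. FGFBP1 (log2 -2.36, limma adjusted p 0.00207), VARS1 (1.90, 0.00207), CARM1 (1.56, 0.0072), CPSF1 (1.41, 0.0161), UCKL1 (1.32, 0.0343), SUPT6H (1.39, 0.0434), ACTB (-1.28, 0.0185) and MB (-1.96, 0.0159) still passed. RPL14, RPS25, RPS27, H4C3 and IFITM1 passed too, at adjusted p of 0.00799, 0.0045, 0.0366, 0.00461 and 0.0421. KRT8 (-0.41, adjusted p 0.614), ST3GAL4 (-0.72, 0.36), VIM (1.51, 0.118), IVL (-1.60, 0.125), AQP3 (-1.67, 0.0814), JSRP1 (1.004, 0.178), COCH (1.65, 0.152), BEST1 (1.71, 0.0953), ZNF771 (1.89, 0.0611), INTS1 (1.28, 0.116) and PLD3 (0.95, 0.108) did not. The count of 581 became 1301 without the plko libraries, 883 without plko 1, 78 without KLF5 1 and 99 without KLF5 2.

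**Figure D2:**
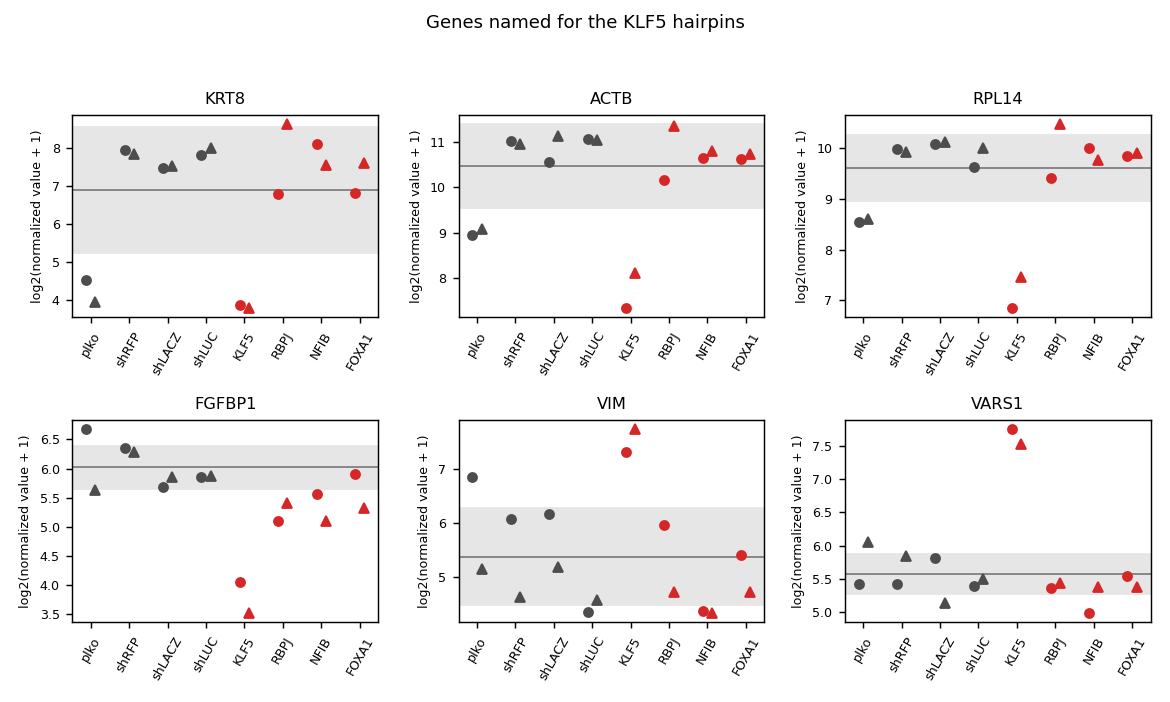
log2(normalized value + 1) of KRT8, ACTB, RPL14, FGFBP1, VIM and VARS1 (vertical axes) in the 16 libraries by construct (horizontal axes), with grey for control and red for targeting constructs, circles for library 1, triangles for library 2, a line at the mean of the 8 controls and a band of 1 SD on either side. Both KLF5 libraries lay outside all 8 controls for each of these genes; KRT8, ACTB and RPL14 were also lower in both plko libraries than in the other 6 controls.

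In lists, squamous differentiation genes were lower with the KLF5 hairpins (median log2 -0.98, camera adjusted p = 0.00211, adjusted p = 0.522 with an estimated correlation). Of 16 members 1, IVL, passed over all genes and 1 adjusted over the list alone. The list median was -0.58 in KLF5 1 and -0.86 in KLF5 2, both inside the control range of -1.45 (plko 1) to 0.44. KLK5, an epidermal protease (-0.94), PI3, the elastase inhibitor elafin (-1.80), and SPRR1B, a cornified envelope protein (0 and 1.17 against 11.9 ± 10.6), did not pass. Mesenchymal transition genes were higher (median 0.65, adjusted p = 0.0161, adjusted p = 0.299 with an estimated correlation): VIM and TNC, the matrix protein tenascin C (1.29, limma adjusted p 0.0136), rose, and 4 of 17 members passed adjusted over the list alone. The matrix glycoproteins THBS1 (1.94) and FN1 (13.5 and 15.2 against 4.02 ± 4.14) did not pass over all genes. The fibroblast markers COL1A1 and DCN were at 27 and 29.2 (controls 6.8 to 25.8) and at 4.27 and 5.83 (controls 0 to 4.22), so a part of RNA from other cells in the higher list was not excluded. Other such markers did not lie above the controls in both KLF5 libraries. COL1A2 was at 2.13 and 4.67 (controls 0 to 4.22), PDGFRA at 2.13 and 3.5 (0 to 5.63) and ENG at 10.7 and 7 (2.21 to 8.84). COL1A1 was also at 24.6 and 32.5 with the NFIB hairpins. Replication-dependent histones and short RNAs were lower (median -0.82, adjusted p = 0.000529, adjusted p = 0.212 with an estimated correlation), with 2 of 8 members lower over all genes, H4C3 and H1-2 (-0.99), and 4 adjusted over the list alone. H2AJ was at -0.81 and H2BC5 at -0.84. Ribosomal proteins were lower (median -0.31, adjusted p = 1.78e-06, adjusted p = 0.689 with an estimated correlation), with 12 of 51 members lower over all genes, among them RPL7A (-1.76), RPL24 (-1.10) and RPS9 (-1.21), and 20 lower and 1 higher adjusted over the list alone, values that are uncertain where reads are shared with pseudogenes. Oxidative phosphorylation, nuclear genes, had a median of -0.21 (adjusted p = 0.0339, adjusted p = 0.849 with an estimated correlation), with COX7A2 (-1.28) and NDUFS6 (-0.97) lower, NDUFA13 (0.91) higher and UQCRH (-0.54) not passing over all genes, and 2 lower and 1 higher adjusted over the list alone. The squamous differentiation, mesenchymal transition, oxidative phosphorylation and ribosomal protein calls were lost with plko as the only control (camera adjusted p 0.75, 0.0636, 0.928 and 0.0722). So were the calls of H1-2 (log2 -0.88, limma adjusted p 0.175), RPL24 (-0.60, 0.104), RPS9 (-0.73, 0.108), COX7A2 (-0.86, 0.0571), NDUFS6 (-0.53, 0.226) and NDUFA13 (0.80, 0.147). THBS1 passed in that setting (2.75, limma adjusted p 0.0365), but its value in plko 1, 2.21, is 1 read, so this fold is uncertain. The oxidative phosphorylation, nuclear genes call was also lost without KLF5 2 (0.149), shLACZ 1 (0.0548) or shLACZ 2 (0.0814).

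Members of other lists passed with the KLF5 hairpins although their list did not, and they were named after their values were seen. AURKA, a mitotic kinase (log2 -1.24), CCNB2, a mitotic cyclin (-0.89), CENPF (-0.92) and PRC1 (-0.82) fell, and the mitosis list had a median of -0.22 (camera adjusted p 0.0633). ITGA6, an integrin of basal cells, fell by 0.90, KRT19 by 1.11, LCN2, the iron-binding lipocalin, by 1.57, and the chaperones HSP90AB1 and DNAJB1 by 1.16 and 1.11. ACAT2 fell by 1.26, SREBF2, a master factor of sterol synthesis, by 1.02, GAPDH by 1.07, ALDOA by 0.95, and the interferon-induced BST2 and SAMD9 by 1.57 and 1.22. E2F1, a driver of S-phase entry, rose by 0.90, NFKB1 by 0.77 and PDIA4 by 0.75. In the Notch pathway list SNW1, a spliceosome protein that binds the Notch complex, fell by 1.32 and HES4, a Notch-responsive repressor, rose by 0.96, and 2 members were higher and 3 lower adjusted over the list alone. With plko as the only control AURKA (log2 -1.19, limma adjusted p 0.0225), CENPF (-1.29, 0.014), ACAT2 (-1.21, 0.0178), SAMD9 (-1.18, 0.0381), E2F1 (0.96, 0.0338) and SNW1 (-1.16, 0.0173) still passed. ITGA6 (-1.01, 0.0828) and HES4 (1.14, 0.0545) did not pass, at folds no smaller than against all controls. CCNB2 (-0.75, 0.125), PRC1 (-0.75, 0.085), GAPDH (-0.78, 0.0691), NFKB1 (0.68, 0.176), PDIA4 (0.69, 0.113), KRT19 (-0.60, 0.194) and SREBF2 (-0.54, 0.288) did not pass either. LCN2 (-0.58, 0.364), HSP90AB1 (-0.41, 0.446), DNAJB1 (-0.35, 0.502), ALDOA (-0.33, 0.514) and BST2 (-0.41, 0.586) were the furthest from passing.

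Targeting RBPJ asked what follows from lowering the transcription factor that acts downstream of Notch, and 3 genes passed, all lower. SERPINB4, a serpin of squamous epithelium, fell by 2.19 on the log2 scale (SE 0.36, limma adjusted p = 0.0203), to 51.2 and 20.4 from 160 ± 56.7 (n = 8), though SERPINB3 and SERPINB4 are near-identical and may share reads. CLEC7A, the beta-glucan receptor dectin-1, fell by 1.81 (SE 0.30, adjusted p = 0.0203), to 25.9 and 9.01 from 56.8 ± 6.77. DHCR7, the enzyme of the last step of cholesterol synthesis, fell by 1.43 (SE 0.25, adjusted p = 0.0417), to 69.6 and 31.3 from 129 ± 17.1. SQLE, squalene epoxidase, was at 76.8 and 39.8 against 146 ± 34.7, and ACAT2, an acetyl-CoA acetyltransferase, at 79.1 and 72.6 against 167 ± 28.6, without passing (adjusted p 0.0927 and 0.109). The higher genes of smallest p, none passing, were HSPA1B, which may share reads with HSPA1A (79 to 119 against 48 ± 4.95), SWI5, APH1A, a gamma-secretase subunit, PPP1R15A, a stress-induced phosphatase subunit, and NDRG4, at log2 1.005, 0.96, 0.99, 1.15 and 1.82. At an unadjusted p under 0.05 there were 593 genes, and edgeR called 0 and DESeq2 26 genes. The count of 3 became 142 without RBPJ 1, 0 without RBPJ 2, shRFP 1 or shRFP 2, and 6 without plko 1. Both RBPJ libraries lay outside the control range for 4.46% of genes, against 4.44% by chance.

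Cholesterol synthesis genes were lower with the RBPJ hairpins (median log2 -0.94, camera adjusted p = 1.09e-30, adjusted p = 0.0873 with an estimated correlation), with 1 of 23 members passing over all genes and 17 adjusted over the list alone, among them DHCR7, SQLE, ACAT2 and IDI1, an isoprenoid isomerase (-1.41). The list median was -1.34 in RBPJ 2 and -0.44 in RBPJ 1, below the lowest control library at -0.17. Mitosis genes were lower (median -0.25, adjusted p = 1.83e-08, adjusted p = 0.212 with an estimated correlation), with 0 of 25 members passing over all genes and 2 adjusted over the list alone, PRC1, of the central spindle (-0.71), and CENPE, a kinetochore motor (-1.28). TOP2A was at -0.83 and HMMR at -0.68. Squamous differentiation genes were lower (median -0.30, adjusted p = 2.3e-05, adjusted p = 0.299 with an estimated correlation), with SERPINB4 passing over all genes and 5 of 16 adjusted over the list alone, among them SERPINB3 (-1.64), S100A8, a calprotectin subunit (-2.04), and KLK7, a desquamation protease (-1.26). The list median was -1.29 in RBPJ 1 and -0.30 in RBPJ 2, both inside the control range of -1.45 (plko 1) to 0.44, and the call was lost without RBPJ 1 (adjusted p 0.351).

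Further lists of the RBPJ comparison passed only with RBPJ 2. Luminal progenitor genes were lower (median -0.38, camera adjusted p = 0.00185, adjusted p = 0.102 with an estimated correlation), with 0 of 16 passing over all genes and 3 adjusted over the list alone: RARRES1, a retinoid-responsive gene (-1.55), CD14 (-1.35) and PROM1 (-1.19), with KRT4 at -1.04. Interferon response genes were lower (median -0.34, adjusted p = 9.26e-06, adjusted p = 0.683 with an estimated correlation), with 4 of 26 adjusted over the list alone and 0 over all genes. OASL was at 7.96 and 0.95 against 18.7 ± 9.01, RIGI, an RNA sensor, at log2 -0.98, IFIT2 at -1.73 and IFIT3 at -1.61. EGF family ligands and immediate MAPK response genes were higher (median 0.37, adjusted p = 0.00661, adjusted p = 0.522 with an estimated correlation), with 0 of 19 members passing over all genes or adjusted over the list alone, and HBEGF at 0.98, FOSL1 at 1.92, AREG at 0.84 and SPRY2 at 0.52. Hypoxia and glycolysis genes were lower (median -0.20, adjusted p = 0.00211, adjusted p = 0.708 with an estimated correlation), with 0 of 23 members passing over all genes or adjusted over the list alone, and LDHA at -0.70, CA9 at -1.85, VEGFA at -0.85 and ERO1A at -0.44. Without RBPJ 2 the adjusted p of these 4 lists became 0.0696 (luminal progenitor), 0.96 (interferon response), 0.874 (EGF family ligands and immediate MAPK response) and 0.0526 (hypoxia and glycolysis). The hypoxia and glycolysis call was also lost without plko 1 (0.117) and, with the direction turned, with the number of detected genes as a covariate (0.856).

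With the NFIB hairpins, which target a nuclear factor I protein, PABPC1, the main cytoplasmic poly(A)-binding protein, was the gene that passed. It was at 274 and 326 against 681 ± 98 in the controls (n = 8), a log2 fold change of -1.17 (SE 0.18, limma adjusted p = 0.0227). PABPC3, a near-identical retrocopy, was at 43.7 and 67.1 against 126 ± 14.4 (adjusted p 0.0735), and since reads can be shared between the copies both values are uncertain. KIF20B, a mitotic kinesin, was at 20.5 and 32.1 against 64.9 ± 18.5, and NRP1, a semaphorin and VEGF co-receptor, at 45.1 and 51 against 96 ± 18, without passing. The higher genes of smallest p, none passing, were HSPA1B (log2 1.13), SLC1A5, a glutamine transporter (642 and 494 against 263 ± 63.1), UCHL1, a deubiquitinase (88.1 and 92.8 against 49.3 ± 7.44), C12orf57 (1.12) and ZNF579 (1.21). At an unadjusted p under 0.05 there were 721 genes, and edgeR called 0 and DESeq2 10 genes. The count of 1 became 0 without NFIB 2, shRFP 1, shRFP 2, shLUC 1 or FOXA1 1, and 2 without KLF5 1, KLF5 2 or shLACZ 1. Both NFIB libraries lay outside the control range for 6.12% of genes, against 4.44% by chance.

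Cholesterol synthesis genes were lower with the NFIB hairpins too (median log2 -0.52, camera adjusted p = 7.36e-09, adjusted p = 0.299 with an estimated correlation). Of 23 members 0 passed over all genes and 4 adjusted over the list alone, among them ACAT2 (-0.83), SQLE (-0.85) and HMGCS1 (-1.005). The list median was -0.781 in NFIB 1 and -0.265 in NFIB 2, with the lowest control library at -0.172. Mitosis genes were lower (median -0.28, adjusted p = 3.43e-06, adjusted p = 0.303 with an estimated correlation), with CENPE at -1.24, CENPA at -0.74, CENPF at -0.61 and HMMR at -0.65. The mitosis median was -0.559 in NFIB 1 and 0.033 in NFIB 2, the latter inside the control range of -0.055 to 0.093. Hypoxia and glycolysis genes were lower (median -0.35, adjusted p = 0.000147, adjusted p = 0.683 with an estimated correlation), with ERO1A at -0.81, LDHA at -0.64, CA9 at -1.96 and BNIP3 at -1.25. The list median was -0.229 in NFIB 1 and -0.308 in NFIB 2, against a control range of -0.295 to 1.22 (plko 1). Unfolded protein and integrated stress response genes were higher (median 0.40, adjusted p = 0.00345, adjusted p = 0.683 with an estimated correlation). PPP1R15A was at 0.93, CHAC1, a glutathione-degrading enzyme, at 1.41, SESN2 at 0.83 and HSPA5, the chaperone BiP, at 0.51. This list's median was 0.639 in NFIB 1 and 0.143 in NFIB 2, both inside the control range of -0.192 to 0.704 (plko 1). Luminal progenitor genes (median -0.35, adjusted p = 0.0277) and Notch pathway genes (median -0.25, adjusted p = 0.0309) were lower, each with an adjusted p = 0.212 with an estimated correlation. The luminal progenitor medians were -0.063 in NFIB 1, inside the control range, and -0.438 in NFIB 2, with the lowest control at -0.183. The Notch pathway medians were -0.088 and -0.123, with the lowest control at -0.118. They were as low in FOXA1 1 (-0.121) and FOXA1 2 (-0.148). PROM1 was at -1.17, EHF at -1.04, KIT at -1.49 and RARRES1 at -0.72, and the receptor NOTCH3 at -0.41, MAML2 at -0.90, the ligand JAG2 at -0.54 and the Notch antagonist NUMB at -0.42. In these 5 lists 0 members passed over all genes or adjusted over the list alone. The mitosis call was lost without NFIB 1 (adjusted p 0.925), as was that of the unfolded protein and integrated stress response (0.255), and the luminal progenitor and Notch pathway calls without NFIB 2 (0.186 and 0.191). The Notch pathway call was also lost without plko 1 (0.0525), and that of hypoxia and glycolysis with the number of detected genes as a covariate (0.574).

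With the FOXA1 hairpins, AGR2, a disulfide isomerase of secretory luminal cells, was the gene that passed. It fell by 2.19 on the log2 scale (SE 0.32, limma adjusted p = 0.00871), to 25.7 and 27 from 129 ± 44.5 (n = 8). S100A7, the epidermal protein psoriasin, was at 101 and 129 against 9.37 ± 6.84 without passing over all genes (log2 3.89, SE 0.71, adjusted p 0.0922). SERPINB4 was at 579 and 350 against 160 ± 56.7 and ZC3H12A, an RNase that degrades cytokine transcripts, at 139 and 153 against 73.4 ± 11.2, with adjusted p of 0.26 and 0.394. SBSN, an epidermal secreted protein, was at 13.2 and 10.5 against 1.39 ± 1.56. The other lower genes of smallest p, none passing, were DPM2 (4.61 and 6.01 against 17.3 ± 4.07), SIM1 (5.27 and 0 against 11.8 ± 3.64), MAP2K7 (15.8 and 16.5 against 38.9 ± 7.96) and HDAC11 (1.98 and 0 against 6.97 ± 2.7). At an unadjusted p under 0.05 there were 552 genes, and edgeR called 1 gene, higher, and DESeq2 3 genes. The count of 1 became 26 without FOXA1 1, 0 without FOXA1 2, and 2 without plko 1 or shLUC 1, and the AGR2 call was lost without FOXA1 2 (limma adjusted p 0.359) and with edgeR. Both FOXA1 libraries lay outside the control range for 5.07% of genes, against 4.44% by chance.

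Squamous differentiation genes were higher with the FOXA1 hairpins (median log2 1.02, camera adjusted p = 1.92e-09, adjusted p = 0.164 with an estimated correlation), with 0 of 16 members passing over all genes and 5 adjusted over the list alone, S100A7, S100A8 (2.29), SERPINB3 (0.98), SERPINB4 (1.57) and SPRR2A, a cornified envelope protein (2.12). The list median was 1.03 and 1.04 in FOXA1 1 and FOXA1 2, above all 8 controls (-1.45 to 0.44), of which plko 1 was the lowest. Basal keratinocyte-type epithelium genes were higher (median 0.34, adjusted p = 0.00198, adjusted p = 0.706 with an estimated correlation), with 0 of 21 passing over all genes or adjusted over the list alone. The basal list median was 0.369 in FOXA1 1 and 0.248 in FOXA1 2, the latter inside the control range of -0.507 to 0.353. In RBPJ 2 it was 0.471. KRT14, a keratin of basal cells, was at 85.6 and 79.6 against 43.6 ± 17.3, KRT15 at log2 0.61, ITGA6 at 0.50 and KRT6A at 1.27. Mature luminal epithelium genes were lower (median -0.23, adjusted p = 0.00105, adjusted p = 0.183 with an estimated correlation), with AGR2 passing over all genes and AGR2 and FOXA1 of 19 adjusted over the list alone. FOXA1 is itself the targeted gene, and without it the list median was -0.21 (camera adjusted p 0.00863, adjusted p = 0.238 with an estimated correlation), a test added after seeing the data. MUC1 was at -0.52 and CA12 at -0.72. With FOXA1 kept in it, the luminal list median was -0.319 in FOXA1 1 and -0.154 in FOXA1 2, the latter inside the control range of -0.201 to 0.161. The basal keratinocyte-type epithelium and mature luminal epithelium calls were lost without FOXA1 1 (adjusted p 0.142 and 0.204).

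**Figure D3:**
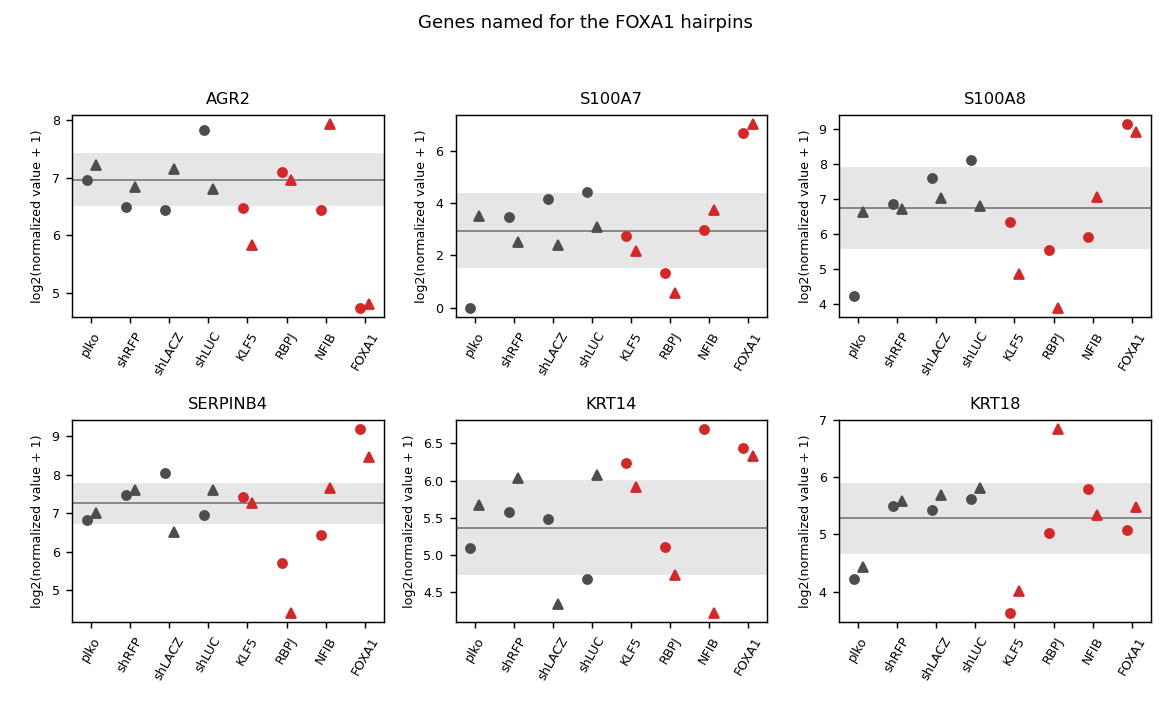
log2(normalized value + 1) of AGR2, S100A7, S100A8, SERPINB4, KRT14 and KRT18 (vertical axes) in the 16 libraries by construct (horizontal axes), with grey for control and red for targeting constructs, circles for library 1, triangles for library 2, a line at the mean of the 8 controls and a band of 1 SD on either side. Of these genes only AGR2 passed the test over all genes with the FOXA1 hairpins; both FOXA1 libraries lay below all controls for AGR2 and above all controls for S100A7, S100A8, SERPINB4 and KRT14.

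Taking the 4 targets together, FGFBP1 (log2 -1.02, SE 0.17) and ACAT2 (-0.85, SE 0.14) were lower than in the controls (limma adjusted p = 0.034 for each, 8 libraries against 8). PABPC1 (-0.62, adjusted p 0.0803), PABPC3 (-0.71) and YWHAZ, a 14-3-3 protein (-0.63), did not pass, nor did TBC1D13 (0.92), HSPA1B (0.71), GRK2 (0.54) or STRN4 (0.54). There were 926 genes at an unadjusted p under 0.05. Cholesterol synthesis (median -0.40, camera adjusted p = 4.72e-15, adjusted p = 0.184 with an estimated correlation), mitosis (-0.20, 5.85e-06, adjusted p = 0.205 with an estimated correlation) and hypoxia and glycolysis genes (-0.28, 7.13e-05, adjusted p = 0.386 with an estimated correlation) were lower, with 1, 0 and 0 members passing over all genes and 10, 3 and 0 adjusted over the list alone. Ribosomal proteins (-0.10) and replication-dependent histones and short RNAs (-0.24) were lower, each at a camera adjusted p of 0.00437 (adjusted p = 0.921 and 0.205 with an estimated correlation), and luminal progenitor genes (-0.10) at 0.0467 (adjusted p = 0.184 with an estimated correlation), with 0 members of each passing over all genes and 0, 1 and 0 adjusted over the list alone. In hypoxia and glycolysis plko 1 was at a list median of 1.22 and the other 7 controls at -0.30 to 0.15, and without plko 1 the call was lost (median -0.14, adjusted p 0.0697). In that setting squamous differentiation (-0.26, 0.00125), oxidative phosphorylation, nuclear genes (-0.12, 0.00956), mature luminal epithelium (-0.10, 0.029) and mesenchymal transition (0.33, 0.0397) passed in addition, at adjusted p = 0.208, 0.524, 0.218 and 0.257 with an estimated correlation. The squamous differentiation mean combines KLF5 and FOXA1 hairpins, whose medians were -0.98 and 1.02. The cholesterol synthesis and mitosis means were not shared by all targets either. In FOXA1 1 and FOXA1 2 the list medians were -0.107 and -0.159 for cholesterol synthesis and 0.033 and 0.042 for mitosis, inside the control ranges. In KLF5 1 and KLF5 2 the cholesterol synthesis medians were 0.096 and -0.336. The count of 2 became 15 without RBPJ 1, 4 without shLACZ 1, 1 without NFIB 2, and 0 without KLF5 2, RBPJ 2, NFIB 1, shRFP 1, shRFP 2, shLACZ 2, shLUC 1, shLUC 2, FOXA1 1 or FOXA1 2.

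Differences between targets were tested directly. The RBPJ and FOXA1 hairpins differed in SERPINB4 (log2 -3.76, RBPJ minus FOXA1), SERPINB3 (-2.62), S100A7 (-5.91), S100A8 (-4.33), CLEC7A (-1.96) and AGR2 (2.25), which were among the 7 genes that passed by limma. The NFIB and FOXA1 hairpins differed in AGR2 (2.41, NFIB minus FOXA1), PABPC1 (-1.39) and PABPC3 (-1.63), and these genes were named after their values were seen. KLF5 differed from RBPJ, NFIB and FOXA1 at 194, 302 and 312 genes, and at 28, 11 and 171 genes with plko as the only control of KLF5. RBPJ and NFIB differed at 0 genes by limma, edgeR and DESeq2, with 156 genes at an unadjusted p under 0.05, and at 21 genes without RBPJ 1 and 1 without NFIB 1. Without RBPJ 1 the 7 genes became 67, without plko 1 13, without shLACZ 1 11, without shLUC 2 3, and without RBPJ 2 or FOXA1 2 1. The 3 genes became 7 without plko 1 or FOXA1 1 and 0 without NFIB 2 or FOXA1 2. The 194, 302 and 312 genes became 21, 45 and 27 without KLF5 1, 54, 64 and 62 without KLF5 2, and 448, 569 and 563 without plko 1. The 194 genes became 446 and 5 without RBPJ 1 and RBPJ 2, 293 without plko 2, 129 without shRFP 1, 126 without shLACZ 2, 127 without shLUC 1 and 117 without FOXA1 1 or FOXA1 2. The 302 genes became 52 and 108 without NFIB 1 and NFIB 2, 182 without shLUC 2 and 168 without FOXA1 1 or FOXA1 2, and the 312 genes 141 and 24 without FOXA1 1 and FOXA1 2. Cholesterol synthesis genes were lower with RBPJ than with FOXA1 hairpins (median difference -0.90, camera adjusted p = 5.91e-17, adjusted p = 0.221 with an estimated correlation), and interferon response genes lower with RBPJ than with NFIB hairpins (-0.72, 2.56e-11, adjusted p = 0.435 with an estimated correlation), with 0 members of either passing over all genes and 5 and 0 adjusted over the list alone.

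**Figure D4:**
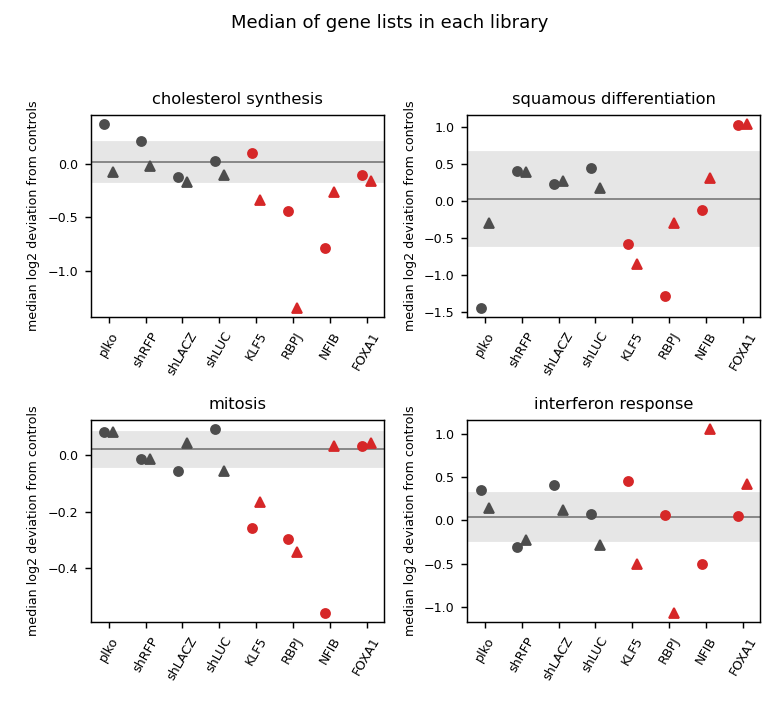
Median over list members of the log2 deviation from the control mean (vertical axes) for cholesterol synthesis, squamous differentiation, mitosis and interferon response genes in the 16 libraries by construct (horizontal axes), with grey for control and red for targeting constructs, circles for library 1, triangles for library 2, a line at the mean of the 8 controls and a band of 1 SD on either side. Interferon response medians were -1.06 in RBPJ 2 and 1.05 in NFIB 2, and their other hairpins lay at 0.07 and -0.50.

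Markers of basal and luminal cells bear on the mix of cell states. KRT5, a basal keratin, was at 2421 and 2271 with KLF5, 2226 and 3535 with RBPJ, 3490 and 2236 with NFIB and 4517 and 2651 with FOXA1 hairpins, against 3015 ± 582 in the controls, and passed in no comparison. KRT14 was at 74.6 and 59.5, 33.6 and 25.6, and 102 and 17.7 with KLF5, RBPJ and NFIB hairpins. KRT18, the luminal partner of KRT8, fell with the KLF5 hairpins (log2 -1.46, limma adjusted p = 0.0358), to 11.4 and 15.2 from 40.6 ± 13.9, but was at -0.50 with plko as the only control (adjusted p 0.51). The mature luminal epithelium list as a whole did not fall, with medians of -0.07 in KLF5 1 and 0.111 in KLF5 2, inside the control range of -0.201 to 0.161. KRT18 was at 31.6 and 114, 54.7 and 39.7, and 32.9 and 43.6 with RBPJ, NFIB and FOXA1 hairpins, and KRT8 at 110 and 395, 275 and 186, and 112 and 192. HES1, a direct Notch target, was at 173 and 228, 277 and 229, 249 and 229, and 236 and 275 with KLF5, RBPJ, NFIB and FOXA1 hairpins, against 306 ± 83.4, and NRARP, another Notch target, at 28.4 and 47.8, 47 and 49.8, 42.4 and 48.9, and 32.9 and 27, against 41.4 ± 12.4, without passing over all genes.

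The lists of asymmetric division and polarity, G1/S and DNA replication, NF-kB and inflammatory cytokines, YAP/TEAD targets, p53 targets and heat shock proteins passed camera with no target. With fry's mixed test, which asks whether members change in either direction, 3 of them passed with KLF5: G1/S and DNA replication (adjusted p 0.00221), NF-kB and inflammatory cytokines (0.0157) and heat shock proteins (0.0019). The mixed test does not compare a list with other genes, and 16.28% of all genes lay outside the control range with KLF5. A pass therefore does not set these lists apart from other genes, and no result with plko as the only control is given for it. Medians in the order KLF5, RBPJ, NFIB and FOXA1 were -0.04, 0.06, -0.10 and 0.06 for asymmetric division and polarity, and -0.01, 0.12, 0.11 and -0.14 for G1/S and DNA replication. They were 0.26, 0.05, -0.06 and 0.17 for NF-kB and inflammatory cytokines, and -0.04, 0.28, 0.01 and 0.13 for YAP/TEAD targets. For p53 targets they were -0.23, 0.22, 0.28 and 0.00, and for heat shock proteins 0.06, 0.07, -0.01 and 0.19. Of the mitochondrially encoded genes 0 of 15 were in the table. Of the fibroblast and endothelial markers 5 of 15 were listed, and COL1A1, the most abundant, lay between 6.8 and 32.5. Of the leukocyte markers 2 of 16 were listed, CD68 between 8.82 and 48.8 and PTPRC between 0 and 3.55. In all, 21 of the 84 list tests passed with camera, 0 with an estimated correlation (12 at an unadjusted p under 0.05) and 0 with fry (12 unadjusted), and the mixed test passed 14.

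Fold changes of different targets were compared across genes, which are not independent replicates. The RBPJ and NFIB fold changes correlated at r = 0.594 over 10826 genes, where unchanged groups against the same controls gave 0.2. With the controls split between them r was 0.315. Their covariance was 0.101 against a simulated 0.0292. The other 5 pairs of targets lay between 0.037 and 0.182 with simulated values of 0.198 to 0.201, and KLF5 and RBPJ, the highest of them, had a covariance of 0.0423. The 2 hairpins of a target, each set against different controls, correlated at 0.44 for KLF5, -0.014 for RBPJ, 0.089 for NFIB and 0.069 for FOXA1. The 24 pairs of hairpins with different targets lay at -0.137 to 0.364 (median -0.005). NFIB 1 gave 0.364 with RBPJ 2, the highest of these, and 0.247 with RBPJ 1. NFIB 2 gave 0.035 with RBPJ 2 and 0.108 with RBPJ 1. The likeness of the RBPJ and NFIB fold changes thus came more from NFIB 1, which kept 61.8% of the control NFIB, than from NFIB 2.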

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

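The tests of shared reads with pseudogenes, of KLF5 and RBPJ transcript loss, of the barcoding batch, of an exchange of RBPJ 1 and of low plko values were chosen only after the results were seen.

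The plko and KLF5 libraries stood apart from the other 12 at 412 genes, against 43 for the next pair of constructs. After thinning every library to the read total of the shallowest, 260 genes parted these 4 libraries from the rest (next pair 42), after correction for GC content of the 3′ end 373 (next pair 44), and among genes with no processed pseudogene 324 (next pair 37), so none of these alone accounts for the pattern. KLF5 in the plko libraries was at 84.5% of the other 6 controls, with plko 1 at 70.6, below these 6 (88.7 to 112.25), and plko 2 at 96.04, inside their range, so loss of the KLF5 transcript stays open. A shared barcoding batch could produce the pattern too, but the labels give the batch of 0 libraries, so these explanations cannot be told apart.

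Cholesterol synthesis genes had a median log2 fold change of -0.94 with the RBPJ hairpins and -1.08 after thinning, so depth does not account for it. The library labelled RBPJ 1 kept most of its RBPJ transcript, at 43.26, yet its list median was -0.44, below the lowest control at -0.17, so whether loss of RBPJ is the cause cannot be told. No library outside the RBPJ group had RBPJ below a bound of 35.36, the lowest being 40.84. This argues against an exchange with a strongly lowered library, and an exchange with a weakly lowered one, or with a sample not used here, stays open.

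Squamous differentiation genes had a median of 1.02 with the FOXA1 hairpins, 0.715 without the plko libraries and 1.05 after thinning, so neither low plko values nor depth accounts for it. An effect of FOXA1 loss may explain it, and an unlabelled batch stays open. The list was lower with KLF5 than with FOXA1 hairpins (median difference -2.31, camera adjusted p = 3.74e-09, adjusted p = 0.221 with an estimated correlation) and lower with RBPJ than with FOXA1 hairpins (-1.20, 6.68e-14, adjusted p = 0.203 with an estimated correlation). Members lower over all genes numbered 4 in each difference. Adjusted over the list alone, 13 were lower and 1 higher in the former and 6 lower in the latter. The KLF5 call of this list was lost with plko as the only control (camera adjusted p 0.75). The difference between KLF5 and FOXA1 hairpins was not tested for lists in that setting. It therefore cannot be parted from what the plko and KLF5 libraries share.

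Among 147 sets of 8 control values, 23 had a library far from the other 7, and 17 of the 23 were plko 1. A rate of 1 in 20 sets would give 7.3. Most genes among these sets were named by tests against these same controls, and lists were taken beside their own members. The sets are thus neither unselected nor independent, and 7.3 is not a calibrated chance count. In plko 1 there were 10659 genes with a read (11079 to 11227 in the other controls). List medians in plko 1 were -1.45 for squamous differentiation (others -0.30 to 0.44), 0.70 for unfolded protein and integrated stress response (-0.19 to 0.17) and 1.22 for hypoxia and glycolysis (-0.30 to 0.15). The hypoxia-responsive CA9, VEGFA, ERO1A and BNIP3 were at 346, 371, 552 and 249 in plko 1 (others 15.1 to 80.3, 78.1 to 135, 203 to 266 and 27.7 to 98.6). HES1 was at 505 (237 to 307), RBPJ at 68.4 (43.1 to 54.9), KIT at 135 (10.1 to 29.7), MAML2 at 37.5 (7.5 to 19.7) and IDI1 at 774 (390 to 434) in plko 1. SESN2 was at 44.1 (16.1 to 27.9), HSPA5 at 567 (233 to 357), FN1 at 13.2 (0 to 5.1) and UCKL1 at 48.5 (22.5 to 33.8) in plko 1. In plko 2 COCH was at 19.8 (5.1 to 12), CPSF1 at 84.9 (38.8 to 59.1) and H2AJ at 66.3 (125 to 175). HSPA1B was at 37.4 in shRFP 1 (45.9 to 52.9), GRK2 at 151 in shRFP 2 (100 to 121) and AGR2 at 225 in shLUC 1 (85.9 to 147).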

How the results depend on the processing

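The setting with plko as the only control of KLF5, the lists without the targeted genes and the splits of whole constructs were chosen only after the result was seen. Of the named genes 40 values changed sign under some setting, none of them a passing gene, 4842 stayed the same, 107 were stronger and 170 weaker. Where counts moved, the cause was not tested. For the 2 genes of the mean of the 4 targets, 3 of 100 splits of single libraries into 8 and 8, the real one included, gave as many (highest other 193), but these splits break up constructs. With constructs kept whole, 4 of 35 splits gave as many (highest other 31), so chance cannot be excluded. Splits of whole constructs that kept plko and KLF5 together gave at most 2 genes, and what sets the split with 31 genes apart was not tested. Among the splits of single libraries, 8 kept the plko and KLF5 libraries on the same side, and the highest count, 193, was among these.

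With DESeq2 the counts were 26 for RBPJ, 10 for NFIB, 3 for FOXA1, 24 for the mean of the 4 targets and 1676 over the pairs of targets, from 3, 1, 1, 2 and 818, and KRT8 with FOXA1 hairpins was at -0.15. With edgeR RBPJ and NFIB had 0 genes and KRT8 with FOXA1 hairpins was at -0.19. With array weights the counts were 1357 for KLF5, 2 for NFIB, 2 for FOXA1, 5 for the mean and 1818 over pairs, and KRT8 with FOXA1 hairpins was at -0.14. An estimated correlation and fry each left 0 of 21 list calls, and without the targeted genes in the lists there were 21. With the number of detected genes as a covariate FOXA1 had 3 genes and the mean 0, HES1 with RBPJ hairpins was at 0.032 and KRT18 with FOXA1 hairpins at 0.033. With the compared groups alone NFIB and the mean had 0 genes. A pseudocount of 5 and quantile normalization each gave 2 genes for FOXA1, and a pseudocount of 0.5 put KRT18 with FOXA1 hairpins at 0. The replicate block gave 523 genes differing among the control constructs, from 326, although replicate numbers did not pair samples (28 pairs of constructs, r from -0.195 to 0.216, median 0.026, 3 over 0.1).

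With controls split between targets the correlations across genes, which are not independent replicates, were 0.032 for KLF5 and RBPJ, 0.008 for KLF5 and NFIB, -0.097 for KLF5 and FOXA1, 0.315 for RBPJ and NFIB, -0.056 for RBPJ and FOXA1 and -0.073 for NFIB and FOXA1. With all controls shared, among genes with a mean of at least 50, KLF5 and RBPJ were at 0.035, KLF5 and NFIB at -0.02 (0.198 and 0.202 simulated with no change). The KLF5 hairpins, each against different controls, were at 0.644 among these genes.

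With plko as the only control of KLF5 the counts were 372 for KLF5, 4 for the mean and 229 over pairs, KLF5 was at -0.76, NRARP with KLF5 hairpins at 0.21, KRT8 with RBPJ at -0.057 and with FOXA1 at -0.56, and KRT18 with NFIB at -0.03. Without the plko libraries the counts were 1301 for KLF5, 6 for RBPJ, 2 for FOXA1, 27 for the mean and 2242 over pairs, with KRT8 at -0.057 for RBPJ and -0.56 for FOXA1 and KRT18 at -0.03 for NFIB. Without the shRFP libraries they were 343 for KLF5, 0 for RBPJ, NFIB and the mean and 461 over pairs, with KRT5 at 0.013 for RBPJ and 0.007 for NFIB and KRT18 at 0.084 for FOXA1. Without the shLACZ libraries the mean had 0 genes, KRT14 was at -0.064 for NFIB and KRT18 at 0.091 for FOXA1. Without the shLUC libraries the counts were 366 for KLF5, 0 for RBPJ, NFIB and the mean and 484 over pairs, with KRT18 at 0.14 for FOXA1.

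Leaving out each library in turn gave 20 to 27 list calls, 78 to 883 genes for KLF5, 0 to 142 for RBPJ, 0 to 2 for NFIB, 0 to 26 for FOXA1, 0 to 15 for the mean, 102 to 931 among control constructs and 101 to 1600 over pairs. The targeted genes ranged from -1.31 to -0.58 for KLF5, -2.44 to -0.23 for RBPJ, -3.12 to -0.65 for NFIB and -2.02 to -0.79 for FOXA1. NRARP with KLF5 hairpins ranged from -0.47 to 0.26. With RBPJ hairpins KRT18 ranged from -0.26 to 1.56, KRT8 from -0.091 to 1.75, KRT5 from -0.41 to 0.25 and AREG from -0.10 to 1.77. With NFIB hairpins KRT5 ranged from -0.41 to 0.24, KRT14 from -1.14 to 1.32 and NUMB from -0.91 to 0.075. With FOXA1 hairpins KRT18 ranged from -0.20 to 0.20, KRT8 from -0.10 to 0.71 and KRT5 from -0.16 to 0.61.

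Beside the losses given with their comparisons, list calls were lost as follows, as camera adjusted p. A filter of 20 gave 0.0961 for mesenchymal transition and 0.0961 for oxidative phosphorylation, nuclear genes, with KLF5 hairpins, and 0.136 for luminal progenitor and 0.223 for Notch pathway with NFIB hairpins. Without the shLACZ libraries oxidative phosphorylation, nuclear genes, was at 0.146 for KLF5 and luminal progenitor at 0.0501 for NFIB, without the shRFP libraries luminal progenitor at 0.0677, and without the plko libraries Notch pathway at 0.0735. The covariate gave 0.0708 for luminal progenitor and 0.143 for Notch pathway with NFIB hairpins, and edgeR 0.0708 for luminal progenitor. Quantile normalization gave 0.05 for Notch pathway with NFIB hairpins. With plko as the only control of KLF5, Notch pathway was at 0.0734 for NFIB and hypoxia and glycolysis at 0.0636 for RBPJ.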

Other observations

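The genes of this part were chosen only after the result was seen. Without RBPJ 1, a fit in which the lone RBPJ 2 library was assumed to vary like the others, 142 genes passed by limma, 17 higher and 125 lower. CX3CL1, a membrane-bound chemokine, was at 7.11 in RBPJ 2 against 63.8 ± 13 in the controls (log2 -2.98, adjusted p 0.000195), and MMP7, a secreted matrix protease, at 11.9 against 65.3 ± 8.21 (-2.36, adjusted p 0.00064). The epithelial receptor gene GPRC5A was at log2 1.28 and the tissue factor gene F3 at 1.40 (adjusted p 0.0195 and 0.039). These values describe 1 library. The RBPJ log2 fold change was -2.44 in this fit, but 1 library cannot part a loss of RBPJ from another effect of its hairpin or sample. Across genes RBPJ 2 correlated at -0.014 with RBPJ 1 and at 0.364 with NFIB 1, each set against different controls. NFIB 1 had RBPJ at 49.88, inside the control range.

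In the KLF5 libraries SNW1 was at 20.6 and 25.7 against 59.5 ± 7.43 and HES4 at 71.8 and 57.2 against 33.2 ± 7.33. Against the plko libraries alone SNW1 passed (log2 -1.16, limma adjusted p 0.0173) and HES4 did not (1.14, adjusted p 0.0545). HES1 was at 173 and 228, below the lowest control at 236.68, without passing over all genes (-0.59). It was at -0.80 with plko as the only control (limma adjusted p 0.0864), but HES1 in plko 1 was at 505, against 237 to 307 in the other controls. HES1 also lay below the lowest control in RBPJ 2 (228.55), NFIB 2 (228.65) and FOXA1 1 (236.36). It did not in RBPJ 1 (276.74), NFIB 1 (248.74) or FOXA1 2 (274.88), so a lower HES1 was not particular to the KLF5 hairpins. NRARP was at -0.10, and at 0.21 with plko as the only control.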
